A study of Homo sapiens with 36 samples.

How the data were processed

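Poly-A RNA of 36 libraries was sequenced on an Illumina HiSeq instrument. The libraries come from 4 experiments of 9 libraries, each with a control arm and 2 targeting arms, and 3 libraries per arm. Hairpin experiments in MDA-MB-468, PANC-1 and WiDr compared a non-silencing hairpin with 2 hairpins, and the guide experiment in WiDr compared a non-targeting guide with 2 guides. Per the submitters' processing notes, reads were aligned with Bowtie2 2.1.0 and counted with RSEM 1.2.15 on hg38, and the deposited values are RSEM expected counts per gene. The gene annotation and the strand setting of that step are not given in the sources used here. The table holds 26475 gene symbols, of which 2349 had no count in any library. All per-sample columns were assigned to a library.

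Expected counts were rounded to whole numbers. Library totals ran from 28371127 to 49237322. Symbols were matched to GENCODE 29 for coordinates, transcript length and GC content, and 23900 (90.3%) matched. Each experiment was fitted on its own with edgeR 4.0.16 in R 4.3.3 (filterByExpr by arm, TMM scaling, robust quasi-likelihood fit), leaving 14641, 15128, 14317 and 14649 genes in MDA-MB-468, PANC-1, WiDr with hairpins and WiDr with guides. Each construct was tested against its control and the constructs against each other with the quasi-likelihood F test. P values were adjusted over genes by Benjamini-Hochberg, and a gene passed at an adjusted p under 0.05. The standard error of a log2 fold change is its size divided by the square root of F. Levels are TMM-scaled CPM, given as mean ± SD of 3 libraries. A gene counted as shared when it passed with both constructs in the same direction.

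Libraries were grouped by their titles. In the guide experiment the genotype field of 4 of the 6 guide libraries names the other guide, and this grouping was run as an alternative. The 3 libraries of an arm were treated as biological replicates, as the design text says. Between replicates of the same arm, chi-square per degree of freedom of the counts was 3.50 to 188, above the level of 1 that repeated sequencing of a library would give. Arms were not paired by replicate number. Correlations of residuals between libraries of the same number ran from -0.22 to 0.64 in MDA-MB-468, against -0.62 to 0.55 between other numbers. In PANC-1 they were -0.67 to 0.13 against -0.34 to 0.50, and in WiDr with hairpins -0.15 to 0.07 against -0.11 to 0.14. With guides they were -0.05 to 0.13 against -0.13 to 0.07. These ranges overlap and do not settle the pairing, and the replicate number was run as a block as an alternative.

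Differences of effects between experiments were tested as an interaction in a fit of 18 libraries, as the mean of both constructs against the control in each experiment. Overlaps of shared genes were compared with independent lists by the hypergeometric test over genes tested in both, with p values adjusted by Benjamini-Hochberg over the 8 overlap tests. That test takes genes as independent and equally likely to pass, so its p values can be too small. Because both constructs share their controls, 20 simulations of 9 libraries with unchanged arms and shared controls were made for each experiment. In addition 200 changed genes were simulated at 1.5-fold, 2-fold and 4-fold to test recovery. Of those, 20.9%, 62.7% and 89.4% passed with both constructs in MDA-MB-468, 14.9%, 59.7% and 90.9% in PANC-1, 68.7%, 82.1% and 95.5% in WiDr with hairpins, and 80.6%, 79.1% and 97.0% with guides, with 0 or 1 false shared gene. An absent call at 1.5-fold is therefore weak evidence in MDA-MB-468 and, at this simulated number of changed genes, in PANC-1. In the real data of PANC-1 and WiDr far more than 200 genes passed. The adjusted threshold was less strict there, so the simulated recovery can be too low.

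The gene lists included mitosis and G2/M, DNA replication and G1/S, nucleotide synthesis, cholesterol synthesis, proteasome subunits, interferon-stimulated genes, NF-kB and inflammatory cytokines, mesenchymal and matrix genes, epithelial junction and keratin genes, ATF4 and unfolded protein response, NRF2 targets, hypoxia and glycolysis, intestinal epithelium markers, basal breast epithelium markers and mitochondrially encoded genes. The last has no member in the table and was not analysed here. The gene addressed by the hairpins and guides is not reported here, nor are 2 lists and 1 other gene that are defined by it. With those 2, 16 lists were tested with camera (limma 3.58.1, preset correlation 0.01) on the mean of both constructs, adjusted over the lists of an experiment. The lists, comparisons, named-gene rule and most alternatives were chosen before the data were examined. A count adjusted over the list alone gives the members that pass when Benjamini-Hochberg is applied to the list's p values for that mean. Named genes were CDKN1A, MDM2, TP63 and TP73, the 10 largest rises and 10 largest falls of shared genes with mean CPM of at least 5 (ranked by the smaller change of the constructs), up to 4 members of each passing list reported by smallest p, and genes shared by all 3 lines.

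Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter, a stricter filter (CPM of 1 in 3 libraries), all 36 libraries in 1 fit, only the 2 groups compared, the replicate number as a block, each library left out, guides by the genotype field, the guide libraries as 1 group, camera with an estimated correlation, and fry. Chosen after seeing the data were a correction of each library's smooth trend on transcript length and GC content (mgcv 1.9-3, pseudocount 0.5), a fit without ribosomal RNA rows, PANC-1 hairpin 1 alone in the comparison of all lines, and the control libraries divided between the constructs.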

Results

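RNA sequencing of poly-A RNA was used to follow gene expression with hairpins or guides in 3 human cancer cell lines. MDA-MB-468 is a basal-like breast cancer line, PANC-1 a pancreatic carcinoma line and WiDr a colorectal adenocarcinoma line. Each line was infected with a lentiviral vector for a non-silencing short hairpin RNA (the control) or for 1 of 2 targeting hairpins. WiDr cells were also given a non-targeting CRISPR guide RNA or 1 of 2 targeting guides. For 4 of the 6 targeting guide libraries 2 label fields name different guides, and the titles were used, by which 5040 genes differed between the guides, against 0 of 15268 by the other field (edgeR quasi-likelihood test, Benjamini-Hochberg). The PANC-1 libraries of hairpin 2 are called the libraries labelled hairpin 2 throughout. These libraries changed like the hairpin 1 libraries (correlation of log2 fold changes 0.901). Hairpins against the same target can also give this, and it does not show that the label is wrong. The 12 groups held 3 biological replicates each, 36 libraries in all, with 28371127 to 49237322 expected counts per library. Ribosomal RNA genes took 2.23% to 8.49% of the counts in MDA-MB-468. In WiDr these genes took 5.38% to 10.2% with hairpin 2 against 1.27% to 2.71% in the other 6 hairpin libraries, and 3.78% to 10.0% in the guide experiment, where the groups overlapped.

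CDKN1A, which encodes the cell cycle inhibitor p21 (chromosome 6, 36676460 to 36687339), went different ways. In WiDr it rose with every construct, from 12.3 ± 1.48 to 20.4 ± 1.07 and 23.6 ± 1.25 CPM with the hairpins (log2 0.74, SE 0.0863, and 0.94, SE 0.0854) and from 8.56 ± 0.417 to 20.2 ± 0.260 and 12.7 ± 0.629 CPM with the guides (1.24, SE 0.0754, and 0.57, SE 0.0777). In PANC-1 it fell from 88.6 ± 7.10 to 63.4 ± 1.28 and 66.3 ± 1.34 CPM (-0.48 and -0.42, SE 0.0811), and in MDA-MB-468 the values of -0.65 (SE 0.149) and -0.45 (SE 0.148) did not pass (edgeR adjusted p = 0.0664 and 0.162). MDM2, which encodes a ubiquitin ligase (chromosome 12, 68808176 to 68850686), rose with both WiDr hairpins (0.28 and 0.18) and passed with no other construct. TP73, a transcription factor gene, rose with PANC-1 hairpin 1 (0.44) and WiDr hairpin 2 (0.43) and fell with guide 1 (-0.79). TP63 had 0 to 18 counts per library and was too low to test within an experiment.

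In MDA-MB-468, where the question was which genes change with both hairpins in breast cancer cells, 109 genes rose and 83 fell with both hairpins. SOSTDC1, a secreted antagonist of BMP and Wnt signalling, rose from 1.96 ± 0.0382 CPM to 11.4 ± 0.303 and 8.74 ± 0.884 CPM (SD, n = 3), log2 fold changes of 2.53 and 2.16 (SE 0.109). NCAM1, a neural cell adhesion molecule, rose by 1.63 (SE 0.146) and 1.86 (SE 0.147), SGK1, a glucocorticoid-induced kinase, by 1.16 (SE 0.0840) and 1.52 (SE 0.0844), and SCGB2A2, a secreted protein of breast epithelium, by 1.61 and 1.71 (SE 0.211). AKR1B1, which encodes aldose reductase, fell from 228 ± 30.1 CPM to 86.4 ± 4.37 and 117 ± 15.8 CPM (-1.40, SE 0.125, and -0.96, SE 0.124). CP, which encodes the copper carrier ceruloplasmin, fell by -1.24 (SE 0.167) and -1.65 (SE 0.171), and the actin-binding gene TAGLN by -0.93 and -0.94 (SE 0.161). Further large rises were those of SLC34A2, NCALD, RNASE1, CCNA1, MME and KCNMA1, with log2 fold changes between 1.15 and 1.91. Further falls were those of PALM, TNNT1, IGFL1, CYP2S1, SEMA6B and RRAGD, between -1.47 and -0.89. Over these genes the adjusted p of either hairpin lay between 3.49e-05 and 0.0388 (edgeR quasi-likelihood test, Benjamini-Hochberg). By hairpin, 332 genes (181 up, 151 down) passed with hairpin 1 and 511 (248 up, 263 down) with hairpin 2 of 14641 tested, and 64 differed between the hairpins. Putting control replicate 1 with hairpin 2 replicates 1 and 3, against the other control and hairpin 2 libraries, gave 4157 genes. That is more than the 511 of the labels and points to a structure of the samples beyond the labels. The 192 shared genes became 467 with DESeq2's Wald test, 469 after correction for transcript length and GC content, 497 with all 36 libraries in 1 fit and 75 with each hairpin fitted alone against the control, and leaving out 1 library gave 69 to 201.

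Of the gene lists, 3 passed camera's test on the mean of both hairpins in MDA-MB-468. At least as many lists passed in 51 of 100 random splits of the 9 libraries, the real one included. In PANC-1, WiDr with hairpins and WiDr with guides this held for 25, 21 and 16 splits. Chance is therefore not excluded for the number of lists in any experiment. Among 15 basal breast epithelium markers, KRT14 (1.17 and 1.08), KRT6B (0.59 and 1.25) and GABRP, a GABA receptor subunit (0.53 and 0.68), rose with both hairpins, none fell with both and 12 did not pass with both. Adjusted over the list alone, 6 rose and 2 fell. The list median was 0.26 with camera adjusted p = 0.000492, and adjusted p = 0.606 with an estimated correlation. KRT5 did not pass with hairpin 1 (0.36, SE 0.0890) and rose with hairpin 2 (0.58, SE 0.0892). Of 32 interferon-stimulated genes, HERC5, an ISG15 ligase, rose with both hairpins (0.91 and 0.80) from 2.11 ± 0.385 CPM, and 31 did not pass with both. Adjusted over the list alone, 8 rose and 1 fell (median 0.18, camera adjusted p = 0.00184, adjusted p = 0.134 with an estimated correlation). CMPK2 (0.69 and 0.65), MX1 (0.30 and 0.19) and IFIT3 (0.41 and 0.55) did not pass the test over all genes. Only 3 intestinal epithelium markers were tested. The cell adhesion gene CEACAM6 rose from 12.4 ± 0.704 to 23.4 ± 0.687 and 28.4 ± 0.484 CPM (1.89-fold and 2.30-fold), also adjusted over the list alone, while KRT20 and LGALS4 lay under 1 CPM. This list had camera adjusted p = 1.73e-05, adjusted p = 0.0422 with an estimated correlation and adjusted p = 0.286 without the filter on low counts. The other 11 lists reported had adjusted p from 0.187 to 0.863.

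In PANC-1, 1924 genes rose and 1672 fell both with hairpin 1 and in the libraries labelled hairpin 2. HTRA1, which encodes a secreted serine protease, rose from 9.56 ± 1.61 CPM to 161 ± 12.2 and 99.8 ± 2.08 CPM (SD, n = 3), log2 fold changes of 4.07 (SE 0.136) and 3.39 (SE 0.132). GNG4, a G protein gamma subunit, rose from 0.525 ± 0.0344 to 15.5 ± 0.940 and 15.2 ± 0.169 CPM (4.87 and 4.84, SE 0.116), the desmosomal cadherin DSC2 by 3.63 and 3.47 (SE 0.156) and the granin SCG2 by 3.62 and 3.44 (SE 0.135). UPK1B, a urothelial tetraspanin, fell from 19.5 ± 1.44 CPM to 1.89 ± 0.159 and 3.18 ± 0.390 CPM (-3.37, SE 0.131, and -2.62, SE 0.125). FGFR2, a fibroblast growth factor receptor, fell by -2.45 (SE 0.169) and -3.14 (SE 0.177), and the homeobox gene DLX3 by -2.76 (SE 0.117) and -2.25 (SE 0.113). Other large rises were those of SYT9, TMEM47, FAM107B, PARM1, KIAA1211 and TIAM1 (3.47 to 5.04), and other falls those of TMEM26, CCM2L, CCNO, ADAMTS1 and PTGS1 (-2.85 to -1.87). Ribosomal RNA45S5 (-2.88 and -3.14) and RNA28S5 (-2.42 and -2.58) were also among the largest falls, and the ribosomal share was 4.61% to 9.60% in the 3 control libraries against 0.838% to 2.60% in the other 6. Over these genes the adjusted p lay between 7.80e-08 and 0.00484 (edgeR quasi-likelihood test, Benjamini-Hochberg). With hairpin 1, 4566 genes passed (2455 up, 2111 down) of 15128 tested, against 5053 (2530 up, 2523 down) in the libraries labelled hairpin 2, and 16 genes differed between the arms. Without control replicate 1 the shared genes numbered 5904, and with the replicate number as a block 2304. Putting control replicate 1 with hairpin 1 replicates 2 and 3, against the other control and hairpin 1 libraries, gave 4203 genes.

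Hypoxia and glycolysis genes rose in PANC-1: 18 of 26 rose in both arms, 1 fell and 7 did not pass in both. NDRG1, a hypoxia-induced gene, rose from 24.4 ± 1.64 to 88.8 ± 3.27 and 103 ± 4.81 CPM (1.86, SE 0.0852, and 2.08, SE 0.0858), the glucose transporter SLC2A1 by 1.02 and 1.25, the enolase ENO2 by 1.68 and 1.93 and PFKFB4, a regulator of glycolysis, by 1.92 and 1.73. Adjusted over the list alone, 21 rose and 2 fell (median 0.67, camera adjusted p = 6.29e-17, adjusted p = 0.0969 with an estimated correlation). Of 22 mesenchymal and matrix genes 11 rose and 2 fell in both arms, with 15 up and 3 down adjusted over the list alone (median 0.85, camera adjusted p = 2.81e-08, adjusted p = 0.0969 with an estimated correlation). The collagen genes COL6A2 (2.12 and 1.95) and COL3A1 (4.29 and 1.78, from 0.380 CPM), the transcription factor SNAI1 (1.37 and 1.36) and the matrix gene TGFBI (2.30-fold and 1.94-fold) were among those that rose. Interferon-stimulated genes rose for 7 of 31, none fell, and 10 rose and 2 fell adjusted over the list alone (median 0.40, camera adjusted p = 0.0206, adjusted p = 0.112 with an estimated correlation). These included HERC5 (1.11 and 0.99), IRF9 (0.81 and 0.65), IFIT2 (0.98 and 0.68) and IFIT3 (0.73 and 0.43). Of 25 genes of the ATF4 and unfolded protein response, 6 rose and none fell, with 9 up adjusted over the list alone, among them the stress gene DDIT4 (1.29 and 1.15), CHAC1 (1.61 and 1.09) and the amino acid synthesis genes ASNS (0.56 and 0.84) and PHGDH (1.05 and 0.69). That list's median was 0.11 with camera adjusted p = 0.0299, and adjusted p = 0.817 with an estimated correlation.

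Proteasome subunits fell in PANC-1: 7 of 31 fell in both arms, none rose, and 28 fell adjusted over the list alone (median -0.42, camera adjusted p = 8.94e-05, adjusted p = 0.817 with an estimated correlation). PSMD11 fell from 300 ± 12.2 to 213 ± 3.84 and 230 ± 3.15 CPM (-0.50, SE 0.0722, and -0.38, SE 0.0721), and PSMD1, PSMD2 and PSMC2 fell by -0.55 to -0.25. Mitotic genes fell for 5 of 25 in both arms, with none up and 14 down adjusted over the list alone. The mitotic kinase AURKA fell by -0.57 and -0.97, cyclin B1 (CCNB1) by -0.56 and -0.97, CCNB2 by -0.37 and -0.80 and CDC20 by -0.39 and -0.78 (list median -0.29, camera adjusted p = 0.00166, adjusted p = 0.252 with an estimated correlation). The other 8 lists reported had adjusted p from 0.209 to 0.964. All 6 passing lists moved together with the higher ribosomal share of the control libraries given for the single genes, and none of the 6 passed with an estimated correlation, while at unadjusted p under 0.05 with that correlation 3 did.

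In WiDr with hairpins, 1761 genes rose and 1844 fell with both. HLA-B, a classical major histocompatibility class I gene, fell from 144 ± 4.30 CPM to 31.5 ± 1.78 and 18.4 ± 0.575 CPM (SD, n = 3), log2 fold changes of -2.19 (SE 0.0569) and -2.97 (SE 0.0596). FGF19, a growth factor gene, fell by -2.10 (SE 0.0582) and -2.04 (SE 0.0578), ATAD3C by -2.37 (SE 0.0887) and -2.33 (SE 0.0878) and the lysosomal membrane gene LAMP3 by -1.93 (SE 0.0796) and -1.48 (SE 0.0765). IGFBP2, an insulin-like growth factor binding protein, rose from 9.73 ± 0.370 to 53.4 ± 6.07 and 28.4 ± 1.84 CPM (2.45, SE 0.0869, and 1.54, SE 0.0881). The water and glycerol channel AQP3 rose by 1.55 (SE 0.0672) and 1.64 (SE 0.0670), the hedgehog ligand IHH by 1.93 (SE 0.101) and 1.28 (SE 0.104) and the long noncoding RNA LINC00261 by 1.26 (SE 0.110) and 2.38 (SE 0.105). Other large rises were those of WNK4, ANKS4B, ETV1, HMGN5, AKR1B10 and DPEP1 (1.15 to 2.34), and other falls those of PDE4C, FAXDC2, FXYD5, FIBCD1, NXPH4 and FUT3 (-2.63 to -1.53). Over these genes the adjusted p lay between 9.01e-15 and 3.43e-06 (edgeR quasi-likelihood test, Benjamini-Hochberg). HLA-B and AKR1B10 have close relatives among which reads can be divided, so their values are uncertain. With hairpin 1, 6871 genes passed (3456 up, 3415 down) of 14317 tested and with hairpin 2, 6403 (3178 up, 3225 down). Between the hairpins 6071 genes differed, and 327 passed with both in opposite directions. Changes were small, since 285 of the 3605 shared genes changed over 2-fold with both, and with all 36 libraries in 1 fit the shared genes numbered 2239. The hairpin control and guide control of WiDr, without a targeting construct, differed for 8946 of 14355 genes. Vector and selection differ between these controls, but differences between separate cultures can be part of the counts given here.

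Interferon-stimulated genes fell in WiDr with hairpins: 19 of 34 fell with both, none rose with both, and 32 fell and 1 rose adjusted over the list alone. The list median was -0.22 with hairpin 1 and -2.10 with hairpin 2 (camera adjusted p = 2.88e-86 for the mean of both, adjusted p = 6.94e-05 with an estimated correlation), and the ribosomal share was higher with hairpin 2, as given for the libraries. MX1, an antiviral GTPase, went from 68.9 ± 2.82 CPM to 61.7 ± 1.18 and 10.3 ± 0.415 CPM (-0.16, SE 0.0545, and -2.74, SE 0.0627). OAS1 (-0.41 and -2.41), PARP9 (-0.69 and -2.07) and XAF1 (-0.61 and -4.29) also fell with both. Mitotic genes rose for 21 of 25 with both hairpins and for all 25 adjusted over the list alone (median 0.44, camera adjusted p = 4.77e-17, adjusted p = 0.00135 with an estimated correlation). AURKA rose from 30.8 ± 1.10 to 59.5 ± 4.05 and 56.7 ± 0.994 CPM (0.95, SE 0.0610, and 0.88, SE 0.0609), and TOP2A (0.64 and 0.58), TPX2 (0.60 and 0.52) and CCNB1 (0.71 and 0.50) rose with it.

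Genes of DNA replication went the other way in WiDr with hairpins: 12 of 26 fell with both, 1 rose, and 16 fell and 3 rose adjusted over the list alone. Their median lay at -0.17 (camera adjusted p = 0.00237, adjusted p = 0.148 with an estimated correlation). The transcription factor E2F1 fell by -0.72 (SE 0.0616) and -0.56 (SE 0.0610), the helicase genes MCM6 by -0.48 and -0.52 and MCM2 by -0.49 and -0.27, and GINS2 by -0.56 and -0.79. Of 26 hypoxia and glycolysis genes 8 fell with both and none rose, with 18 down adjusted over the list alone (median -0.22, camera adjusted p = 0.000208, adjusted p = 0.227 with an estimated correlation), among them SLC2A1 (-0.63 and -0.65), ENO2 (-0.70 and -0.79), LDHA (-0.40 and -0.58) and VEGFA (-0.42 and -0.27). The other 10 lists reported had adjusted p from 0.0600 to 0.981. For 13 intestinal epithelium markers the median was 0.37 but the test's direction was down (adjusted p = 0.981).

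In WiDr with guides, 1242 genes rose and 917 fell with both. DHRS9, a retinol dehydrogenase gene, rose from 4.22 ± 0.0277 CPM to 23.0 ± 0.603 and 8.46 ± 0.341 CPM (SD, n = 3), log2 fold changes of 2.45 (SE 0.0805) and 1.00 (SE 0.0856). MUC2, the main secreted mucin of goblet cells, rose by 1.41 (SE 0.118) and 0.85 (SE 0.120), CAV1, the caveolae protein gene, by 1.70 (SE 0.0917) and 0.97 (SE 0.0948) and the aldo-keto reductase AKR1C2 by 1.47 (SE 0.0580) and 0.82 (SE 0.0583). IGFBP2, which rose with the hairpins, fell from 15.5 ± 1.01 to 3.09 ± 0.137 and 6.79 ± 0.904 CPM (-2.32, SE 0.109, and -1.19, SE 0.100). CD74, the invariant chain of class II antigen presentation, fell by -1.36 (SE 0.0802) and -1.43 (SE 0.0810), the Wnt feedback inhibitor NKD1 by -1.31 (SE 0.141) and -2.02 (SE 0.147) and P-cadherin (CDH3) by -1.56 (SE 0.102) and -1.32 (SE 0.101). Other large rises were those of HSD17B2, RGS16, ITPKA, MFNG, IL20RB and RAB27B (0.84 to 1.62), and other falls those of KIRREL, GCNT1, ZNF618, SCD5, NES and SBK1 (-2.03 to -0.92). Over these genes the adjusted p lay between 2.55e-12 and 0.000291 (edgeR quasi-likelihood test, Benjamini-Hochberg). With guide 1, 6100 genes passed (3133 up, 2967 down) of 14649 tested and with guide 2, 3731 (2071 up, 1660 down), 5040 differed between the guides, and 106 of the 2159 shared genes changed over 2-fold with both. With all 36 libraries in 1 fit 680 were shared (304 up, 376 down), with the guides named by the other label field 126, and without control replicate 2 or 3 there were 1413 or 1406. The difference between the WiDr control arms given for the hairpins limits these counts too.

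Interferon-stimulated genes fell in WiDr with guide 2: the list median was 0.04 with guide 1 and -1.10 with guide 2, 8 of 34 fell with both, none rose with both, and 33 fell adjusted over the list alone. For the mean of both guides camera adjusted p = 5.92e-53, and adjusted p = 3.09e-05 with an estimated correlation. IFIT1 fell from 167 ± 1.88 to 120 ± 5.64 and 59.7 ± 1.04 CPM (-0.47, SE 0.0481, and -1.48, SE 0.0498), MX1 fell by -0.19 and -1.40 and OAS2 by -0.14 and -1.54, while IFI44L passed with guide 2 alone (-0.12 and -2.19). With guide 1, 11 members of the list rose and 8 fell, and with guide 2 all 34 fell. Genes of the ATF4 and unfolded protein response rose for 15 of 24 with both guides, none fell, and 22 rose adjusted over the list alone (median 0.34, camera adjusted p = 3.08e-21, adjusted p = 0.0129 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, rose from 802 ± 20.9 to 1606 ± 22.3 and 921 ± 29.7 CPM (1.00, SE 0.0474, and 0.20, SE 0.0470), DNAJB9 by 1.29 and 0.32, HERPUD1 by 0.96 and 0.36 and ATF3 by 0.79 and 0.38. NRF2 targets rose for 8 of 24, none fell, and 19 rose adjusted over the list alone (median 0.23, camera adjusted p = 8.03e-10, adjusted p = 0.0112 with an estimated correlation), among them ferritin heavy chain (FTH1, 0.81 and 0.36), OSGIN1 (0.94 and 0.39) and AKR1C1 (0.83 and 0.16). FTH1 and the AKR1C genes have near-identical copies, so their values are uncertain.

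Epithelial junction and keratin genes rose for 10 of 25 with both guides, none fell, and 14 rose and 1 fell adjusted over the list alone (median 0.19, camera adjusted p = 1.44e-06, adjusted p = 0.0262 with an estimated correlation). They included the epithelial transcription factors ELF3 (0.75 and 0.24) and OVOL1 (0.67 and 0.36), the tight junction gene CLDN1 (0.80 and 1.17) and KRT7 (1.59 and 0.37). Of 13 intestinal epithelium markers 4 rose and none fell with both, with 6 up and 4 down adjusted over the list alone (median 0.18, camera adjusted p = 0.0274, adjusted p = 0.206 with an estimated correlation). KRT20 rose from 264 ± 6.90 to 674 ± 30.4 and 349 ± 13.6 CPM (1.35, SE 0.0507, and 0.40, SE 0.0501), CEACAM6 by 0.90 and 0.28 and LGALS4 by 0.43 and 0.57, whereas the brush border gene VIL1 fell with guide 1 (-0.62) and did not pass with guide 2 (0.12). Of 31 proteasome subunits 7 rose, none fell, and 14 rose and 2 fell adjusted over the list alone, among them PSMA5 (0.39 and 0.23), PSMD7 (0.35 and 0.22), PSMA6 (0.30 and 0.20) and PSMD14 (0.24 and 0.21). That list's median was 0.13 with camera adjusted p = 0.0117, adjusted p = 0.526 with an estimated correlation and adjusted p = 0.135 after the length and GC correction.

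In WiDr with guides, 5 of 26 genes of DNA replication fell with both and 1 rose, with 19 down and 1 up adjusted over the list alone (median -0.25, camera adjusted p = 3.99e-09, adjusted p = 0.0108 with an estimated correlation). By guide, the median was -0.48 with guide 1 (camera adjusted p = 1.13e-15) and -0.02 with guide 2 (camera adjusted p = 0.358). MCM2 fell from 218 ± 5.62 to 134 ± 1.86 and 190 ± 10.9 CPM (-0.70, SE 0.0499, and -0.20, SE 0.0495) and UHRF1 fell by -0.56 and -0.15, while CDC45 (-0.68 and -0.03) and MCM5 (-0.76 and -0.09) passed with guide 1 alone. Of 25 mitotic genes 1 rose and 1 fell with both, with 4 up and 8 down adjusted over the list alone (median -0.30 with guide 1 and 0.12 with guide 2, camera adjusted p = 0.0478 for the mean, adjusted p = 0.273 with an estimated correlation). By guide, the mitotic list was directed down with guide 1 (camera adjusted p = 9.55e-09) and up with guide 2 (camera adjusted p = 0.000776). TOP2A (-0.77 and -0.01), NUSAP1 (-0.56 and 0.09) and CENPF (-0.65 and -0.16) passed with guide 1 alone, and MKI67 passed with both (-0.72 and -0.20), although its guide 2 value was 0.01 after the length and GC correction. Of 24 genes of nucleotide synthesis 2 rose and none fell with both, with 3 up and 10 down adjusted over the list alone. Their test was directed down (median -0.09, camera adjusted p = 0.0362, adjusted p = 0.273 with an estimated correlation), with -0.26 for guide 1 (camera adjusted p = 5.01e-06) and 0.07, directed up, for guide 2 (camera adjusted p = 0.152). RRM2 (-0.80 and -0.04), RRM1 (-0.54 and 0.03), PRPS2 (-0.72 and -0.14) and CAD (-0.37 and -0.17) passed with guide 1 alone. The other 5 lists reported had adjusted p from 0.0893 to 0.636.

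**Figure D1:**
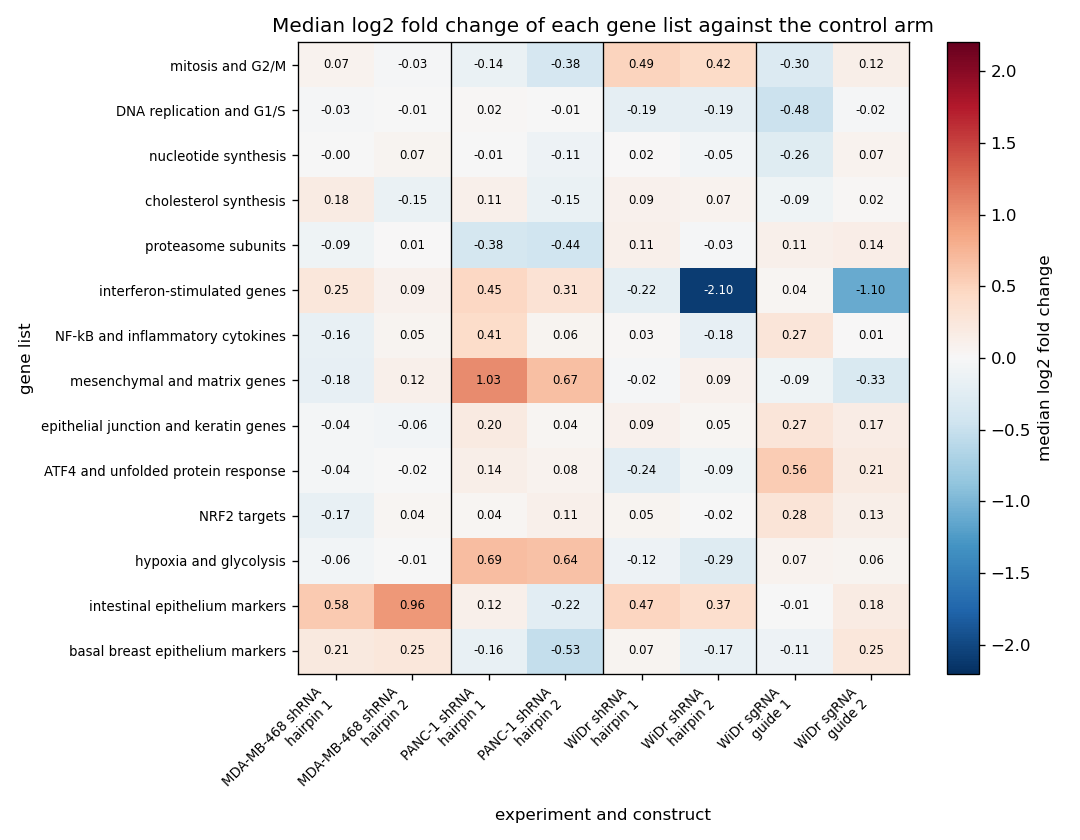
Median log2 fold change against the control arm (colour and printed value) of each gene list (rows) with each construct (columns). The lowest medians are those of the interferon-stimulated genes with hairpin 2 (-2.10) and guide 2 (-1.10) in WiDr, and the mesenchymal and hypoxia lists are highest in PANC-1, where the columns named hairpin 2 are the libraries so labelled.

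Lists of cholesterol synthesis and of NF-kB and inflammatory cytokines passed the test on the mean of both constructs in no experiment. Tests of lists with single constructs used the preset correlation alone and were not run with an estimated correlation. With single constructs of MDA-MB-468, cholesterol synthesis genes were directed up with hairpin 1 (median 0.18, camera adjusted p = 4.81e-05) and down with hairpin 2 (-0.15, adjusted p = 0.0402). Their median for the mean of both was 0.04. NF-kB genes were directed down with MDA-MB-468 hairpin 1 (-0.16, adjusted p = 0.0465) and up with WiDr guide 1 (0.27, adjusted p = 0.0280). Among lists that passed on the mean, the construct 1 and 2 values of camera adjusted p passed with 1 construct alone for interferon-stimulated genes in MDA-MB-468 (1.29e-05 and 0.168) and PANC-1 (0.00351 and 0.161) and for mitotic (0.0869 and 1.22e-05) and ATF4 and unfolded protein response genes (0.00385 and 0.231) in PANC-1. The same held with WiDr guides for interferon-stimulated genes (0.762 and 8.78e-216), intestinal markers (0.235 and 0.00140) and proteasome subunits (0.135 and 0.00232). Of lists that did not pass on the mean, NRF2 targets (down, adjusted p = 4.81e-05) and mitotic genes (up, adjusted p = 0.0465) passed with MDA-MB-468 hairpin 1, and mesenchymal genes (down, adjusted p = 0.00887) with WiDr guide 2. On the mean, cholesterol synthesis genes came nearest in WiDr with hairpins, where 8 of 23 rose with both and none fell (median 0.06, adjusted p = 0.0600), and had adjusted p of 0.530, 0.797 and 0.636 in MDA-MB-468, PANC-1 and WiDr with guides. Genes of NF-kB and inflammatory cytokines had adjusted p of 0.863, 0.209, 0.146 and 0.184 in the same experiments, in the order MDA-MB-468, PANC-1, WiDr hairpins and WiDr guides.

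The constructs of each experiment shared many calls. In MDA-MB-468 the 109 genes up and 83 down with both hairpins compare with 3.07 and 2.71 from independent lists, in PANC-1 the 1924 and 1672 with 411 and 352, in WiDr with hairpins the 1761 and 1844 with 767 and 769, and with guides the 1242 and 917 with 443 and 336. Simulated unchanged groups that share their 3 simulated controls gave at most 1 shared gene in any of 20 simulations. Each gene was drawn independently there, so shifts of whole libraries are left out and the simulated levels can be too low. Random splits of the real libraries, which can still hold part of the real effects, gave up to 85, 3459, 1961 and 553 shared genes. Across genes, which are not independent replicates, the log2 fold changes of the constructs had a Pearson correlation of 0.676, 0.901, 0.575 and 0.511 in that order, against means of 0.496, 0.496, 0.474 and 0.478 and maxima of 0.563, 0.545, 0.578 and 0.571 in the simulations, so both WiDr correlations lie within the simulated range. The covariances were 0.117, 0.461, 0.151 and 0.0944 against means of 0.0346, 0.0323, 0.0186 and 0.0231. With the 3 control libraries divided between the constructs, 1 against 2 in each of 6 ways, the shared genes numbered 19 to 210, 1700 to 2393, 1992 to 2480 and 571 to 1163, in each division above the number from its independent lists (at most 25.4, 1027, 920 and 328), and the correlations 0.114 to 0.367, 0.497 to 0.722, 0.378 to 0.411 and 0.225 to 0.309. A lone control library is taken there to vary like the other groups.

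**Figure D2:**
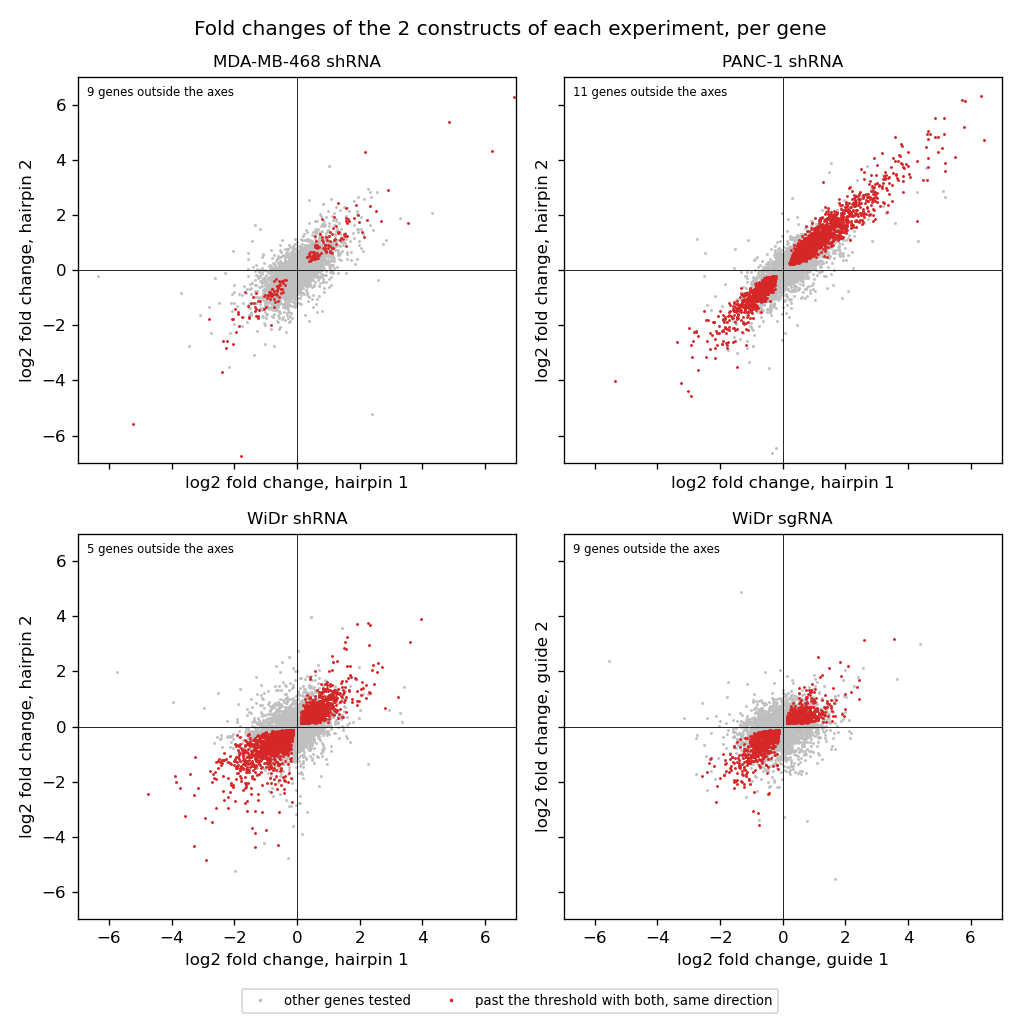
Log2 fold change of construct 2 (y axis) against construct 1 (x axis) for every gene tested in each experiment, with genes past the threshold with both constructs in the same direction in red. The PANC-1 arms lie along the diagonal (correlation 0.901), and WiDr spreads more.

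Across the lines, the shared genes were few. Between MDA-MB-468 and PANC-1, 14 genes rose in both (7.20 from independent lists, hypergeometric test, Benjamini-Hochberg adjusted p = 0.0209) and 7 fell in both (7.36, adjusted p = 0.702), while 33 went opposite ways against 14.6 from independent lists. Opposite directions were thus in excess too, so the 14 genes are not by themselves a sign of shared effects. Between MDA-MB-468 and WiDr with hairpins, 8 rose (7.58, adjusted p = 0.658) and 21 fell (7.56, adjusted p = 1.64e-05), while 12 went opposite ways against 15.2. These overlaps move with single libraries and models: with 1 library left out the 21 genes shared with PANC-1 became 6 to 28 and the 29 shared with WiDr 10 to 36, and with DESeq2's Wald test there were 67 and 76. Between PANC-1 and WiDr with hairpins, 196 rose (188, adjusted p = 0.433) and 191 fell (201, adjusted p = 0.801), while 511 went opposite ways against 389 from independent lists. In all 3 lines, ARRDC3, an arrestin-domain gene, rose with both hairpins: from 16.3 ± 2.59 CPM by 1.06 and 0.70 in MDA-MB-468, from 44.2 ± 3.06 CPM by 1.71 and 1.98 in PANC-1 and from 26.6 ± 1.52 CPM by 0.80 and 0.79 in WiDr. C10orf54, which encodes the immune checkpoint protein VISTA, fell in all 3 lines, by -0.51 and -0.83, -1.07 and -0.94, and -0.98 and -1.09. Independent lists would give 0.596 genes up and 0.806 down in all 3. With the WiDr guides C10orf54 rose instead (0.89 and 0.25), and ARRDC3 rose with guide 1 (0.72) and had -0.01 with guide 2. With PANC-1 hairpin 1 alone 4 genes were shared, GNAI1 (up) among them. The all-line count was 13 with DESeq2's Wald test, 14 after the length and GC correction and 17 with all 36 libraries in 1 fit, and 0 to 5 when 1 library was left out.

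The hairpin and guide experiments in WiDr shared 212 genes up (153 from independent lists, adjusted p = 9.76e-07) and 200 down (115, adjusted p = 2.34e-15), and 212 went opposite ways against 270. With all 36 libraries in 1 fit 67 rose and 108 fell in both. The effects themselves, as the mean of both constructs against the control, differed for 6189 of 14880 genes between these experiments (2918 higher and 3271 lower with hairpins; edgeR quasi-likelihood test of the interaction, Benjamini-Hochberg). IGFBP2 had the log2 difference 3.76 (SE 0.117, edgeR adjusted p = 4.90e-17) and C10orf54 -1.60 (SE 0.0999, edgeR adjusted p = 1.78e-11). Between MDA-MB-468 and PANC-1 the effects of 3905 genes differed (1983 higher and 1922 lower in MDA-MB-468), between MDA-MB-468 and WiDr with hairpins 2910 (1479 and 1431) and between PANC-1 and WiDr with hairpins 6044 (3403 higher and 2641 lower in PANC-1). AURKA had differences of -0.90 (SE 0.0823) between MDA-MB-468 and WiDr and -1.63 (SE 0.0794) between PANC-1 and WiDr, and HLA-B 2.18 (SE 0.145) and 2.39 (SE 0.163). The calls of WiDr are helped by a smaller spread between its replicates, with a biological coefficient of variation of 0.0631 and 0.0638 against 0.151 in both MDA-MB-468 and PANC-1, so counts of genes are not comparable between lines as effect sizes.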

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

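Tests of whether effects differ between experiments were planned, and so were the random splits below. The tests of explanations for the PANC-1 arms and for the interferon-stimulated genes, and the 10-split tests of single constructs, were chosen only after the results were seen.

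Effects differed between experiments by an interaction test (edgeR quasi-likelihood test, Benjamini-Hochberg) for 3905 genes between MDA-MB-468 and PANC-1, 2910 between MDA-MB-468 and WiDr with hairpins, 6044 between PANC-1 and WiDr with hairpins and 6189 between WiDr with hairpins and with guides. The highest of the other 79 of 80 random splits gave 3654, 1645, 2796 and 988 genes, and 1 split of 80, the real one, gave as many. This argues against chance alone for each pair. Between MDA-MB-468 and PANC-1 the margin was small (3905 against 3654), so a structure of the samples is not excluded as a source of many of those genes. CDKN1A differed by -1.40 (SE 0.149) between MDA-MB-468 and WiDr and -1.24 (SE 0.0972) between PANC-1 and WiDr, MDM2 by -0.34 (SE 0.0863) between PANC-1 and WiDr, and TP73 by 0.86 (SE 0.140) between the WiDr experiments. TP63 had a fitted difference of -3.98 between MDA-MB-468 and PANC-1, which depends on the prior count, since the PANC-1 controls held 3, 0 and 0 counts.

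Gene lists also differed by the same contrast, with medians of log2 differences and adjusted p of camera with an estimated correlation. Hypoxia and glycolysis genes differed by -0.70 between MDA-MB-468 and PANC-1 (adjusted p = 0.0246) and by 0.87 between PANC-1 and WiDr (adjusted p = 0.000488). Mitotic genes differed by -0.42 between MDA-MB-468 and WiDr (adjusted p = 0.000113), -0.63 between PANC-1 and WiDr (adjusted p = 0.000488) and 0.52 between WiDr hairpins and guides (adjusted p = 7.17e-05). Interferon-stimulated genes differed by 1.37 (adjusted p = 1.71e-07), 1.63 (adjusted p = 2.75e-06) and -0.69 (adjusted p = 4.25e-05) in those pairs. Between MDA-MB-468 and WiDr, DNA replication genes differed by 0.15 (adjusted p = 0.0334) and intestinal markers by a median of -0.39, although their test was directed up (adjusted p = 0.0266). NF-kB genes differed by 0.45 between PANC-1 and WiDr (adjusted p = 0.0436), and ATF4 and unfolded protein response genes by -0.47 between WiDr hairpins and guides (adjusted p = 0.0319).

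In PANC-1 the libraries labelled hairpin 2 changed like those of hairpin 1. A handling difference of the control libraries stays open and cannot be told apart from the treatment: every control library had a higher ribosomal share than the other 6, by at least 2.01 percentage points.

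Interferon-stimulated genes fell most with hairpin 2 and guide 2 in WiDr, for 33 and 34 of 34 genes. Transcript length and GC trends are argued against, since the medians stayed at -2.13 and -1.07 after the correction. Separate derivation of the cultures was not tested for this list.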

How the results depend on the processing

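The length and GC correction, PANC-1 hairpin 1 alone and the divided controls were chosen only after the results were seen. Counts below moved by over 1.5 times, and the cause was not tested. With DESeq2's Wald test, MDA-MB-468 had 805 genes for hairpin 1, 1104 for hairpin 2 and 467 shared, with 67 shared with PANC-1, 76 with WiDr and 13 in all 3 lines. With only the compared groups fitted, MDA-MB-468 had 177, 127 and 75, and PANC-1 hairpin 1 had 2966. With the length and GC correction, MDA-MB-468 had 770, 1214 and 469, and 280 between hairpins, PANC-1 126 between arms, and the overlaps were 73 (MDA-MB-468 and PANC-1), 78 (MDA-MB-468 and WiDr), 629 (PANC-1 and WiDr) and 14 (all lines). With all 36 libraries in 1 fit, MDA-MB-468 had 900, 1268 and 497, WiDr hairpin 2 3964 with 2239 shared, the guides 3620 and 1261 with 680 shared, and the overlaps were 111, 80, 175 (WiDr hairpins and guides) and 17. With the replicate number as a block, MDA-MB-468 had 35 between hairpins, PANC-1 2943, 3254, 2304 shared and 5 between arms, and the overlaps were 9, 231 (PANC-1 and WiDr) and 1 in all lines. Without the filter 1 gene was left in all lines, and with PANC-1 hairpin 1 alone 4. Dividing the controls between the constructs left fewer control libraries per contrast and none in common, and these changes were not told apart. The shared genes were then 19 at the lowest in MDA-MB-468 (210 at the highest), 1700 to 2393 in PANC-1, 1992 at the lowest in WiDr with hairpins and 571 to 1163 with guides.

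With guides by the genotype field there were 1353, 127 and 126 genes, and 0 between guides of 15268 tested by edgeR, with 269 at unadjusted p under 0.05. With an estimated correlation 1, 0, 2 and 5 lists passed in MDA-MB-468, PANC-1, WiDr with hairpins and with guides, and with fry 10 in WiDr with hairpins. MKI67 with guide 2 reversed with the length and GC correction, to 0.00635 (adjusted p = 0.899).

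Leaving out 1 library gave 85 to 331, 167 to 567, 69 to 201 and 11 to 38 genes in MDA-MB-468 for hairpin 1, hairpin 2, both and between hairpins. Counts lower by over 1.5 times came without control replicate 3 (112, 216 and 77), without hairpin 1 replicates 1, 2 and 3 (115, 85 and 92 for hairpin 1, 86, 69 and 70 for both) and without hairpin 2 replicates 1, 2 and 3 (167, 315 and 259 for hairpin 2, 93 for both without replicate 1). Between hairpins these gave 16, 11 and 11, and 11, 38 and 18. In PANC-1 the ranges were 2851 to 6797, 3116 to 7958, 2432 to 5904 and 5 to 9. The first 3 were highest without control replicate 1, and between arms each left-out library of either arm gave 9 or fewer. Without hairpin 1 replicate 2 there were 2851 for hairpin 1, and without the first library labelled hairpin 2, 3116 for that arm. Without the second there were 3133, and without control replicate 2 or 3, 3365 or 3338. Guide 2 gave 2436 to 4138 and both guides 1406 to 2337, low without control replicate 2 (2468 and 1413) or 3. The overlaps ran from 6 to 28 (MDA-MB-468 and PANC-1), 10 to 36 (MDA-MB-468 and WiDr), 264 to 627 (PANC-1 and WiDr, 627 without PANC-1 control replicate 1) and 0 to 5 in all lines. The overlap of MDA-MB-468 with PANC-1 was 13 and 6 without MDA-MB-468 control replicates 2 and 3, 8 without each hairpin 1 replicate and 7, 10 and 11 without the hairpin 2 replicates. With WiDr it was 11 without control replicate 3, 15, 10 and 11 without the hairpin 1 replicates and 14 without hairpin 2 replicate 1. In all lines 0 genes were left without MDA-MB-468 control replicate 3 or hairpin 2 replicate 1 or 2, 1 without the other hairpin libraries of MDA-MB-468 and 5 without PANC-1 control replicate 1. Other counts of genes and lists stayed within 1.5 times under each alternative run, as did all counts with DESeq2 size factors, the stricter filter and without ribosomal RNA rows. Of single named genes and lists, 2410 values with a library left out kept their call, 141 lost the call and 8 gained it. With guides by the genotype field 61 values of single named genes kept their call and 63 lost it. A value that passed in neither fit counted as kept even where its direction changed. The libraries themselves group by title: on the first principal component the guide 1 libraries lie at 27.9 to 29.4 and those of guide 2 at -9.57 to -7.46, and the genotype field mixes these groups. Which guide either group carries was not tested. With an estimated correlation 8 passing lists kept the call and 15 lost it, and under each other alternative at most 24 single values lost theirs. No scaling moved the median of all genes by over 0.1 log2.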

Other observations

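The lists of antigen presentation genes and Wnt feedback targets, the tests of the spread between replicates without splits, and the 10-split tests of single constructs were chosen only after the results were seen. HLA-B, CD74 and NKD1, members of these gene lists, were by then among the largest falls in WiDr. Tests of these gene lists in WiDr are therefore not independent evidence.

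Antigen presentation genes fell with both hairpins in WiDr, 14 of 15 tested, with medians of -0.73 and -1.36 (camera adjusted p = 8.65e-42, and 0.00498 with an estimated correlation). HLA-C fell by -1.43 (SE 0.0633) and -1.80 (SE 0.0641), B2M, the class I light chain, by -0.71 (SE 0.0709) and -1.22 (SE 0.0716), the peptide transporter TAP1 by -0.82 and -2.37 and the immunoproteasome subunit PSMB9 by -1.67 and -2.79. HLA genes share sequence, so their separate values are uncertain. With guides 2 of 16 fell with both, CD74 and HLA-DMA, and TAP1 rose with guide 1 (0.42) and fell with guide 2 (-1.04). The list had medians of 0.24 and -0.66 with the guides and passed directed down (camera adjusted p = 0.000330), but not with an estimated correlation (adjusted p = 0.224). In MDA-MB-468 none of 14 passed with both, and the list passed directed down (medians -0.32 and -0.20, camera adjusted p = 0.00500) but not with an estimated correlation (adjusted p = 0.244). In PANC-1 1 of 16 passed with both, up (camera adjusted p = 0.607, and 0.804 with an estimated correlation).

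Wnt feedback targets fell for 7 of 14 with both guides, among them NKD1, the stem cell receptor LGR5 (-0.86 and -0.44) and ZNRF3 (-0.66 and -0.29), while MYC rose (0.54 and 0.23), and the list passed directed down (camera adjusted p = 7.16e-05), but not with an estimated correlation (adjusted p = 0.0533). AXIN2 passed with guide 1 alone (-0.52 and -0.10), and DKK1 fell with guide 1 (-0.31) and rose with guide 2 (0.97). With WiDr hairpins 4 of 13 fell and 1 rose (camera adjusted p = 0.0921, and 0.224 with an estimated correlation), including AXIN2 (-0.74 and -0.25) and CCND1 (-0.60 and -0.65) among those that fell. In MDA-MB-468 none of 10 passed with both (camera adjusted p = 0.138, and 0.224 with an estimated correlation), and in PANC-1 2 rose and 1 fell of 11 (camera adjusted p = 0.148, and 0.244 with an estimated correlation). Those that rose in PANC-1 were AXIN2 (2.03 and 1.84) and NOTUM (2.18 and 1.78), and TCF7 fell (-0.50 and -0.58).

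Replicates of MDA-MB-468 and PANC-1 spread more than those of WiDr, with a biological coefficient of variation of 0.151 in both against 0.0631 and 0.0638, and 0.118 and 0.107 without control replicate 1. Transcript length and GC trends are argued against as the whole source, since the correction, made in WiDr too, removed 14.8% and 12.2% of the excess over the WiDr mean (13.4% to 16.1% and 10.5% to 15.2% with 1 library left out). Ribosomal reads stay open: leaving out the ribosomal RNA genes removed none of the excess (-0.535% at most), but it moved the spread little in any experiment. Splits that put control replicate 1 with 2 hairpin libraries gave 4157 genes in MDA-MB-468 and 4203 in PANC-1, which points to a structure of the samples, and after the correction 2639 and 3740, which argues against these trends as its whole source. No biological explanation was tested.

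Separately derived WiDr cultures may differ by many genes without a targeting construct, a hypothesis tested on the control arms. Of 14355 genes, 8946 differed between guide control and hairpin control (4464 higher and 4482 lower with the guide control), 994 of them over 2-fold. That is more than any WiDr construct gave against its control, in line with the hypothesis, although vector and selection differ between these arms too. The 10 splits of these libraries are too few, with 8946 for the real split and 0 for the highest other.

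Of 100 random splits of the 9 libraries of each experiment, 1, the real one, gave as many shared genes, the lowest share these splits can reach. The counts were 192 against 85 for the highest other in MDA-MB-468, 3596 against 3459 in PANC-1, 3605 against 1961 in WiDr with hairpins and 2159 against 553 with guides. This argues against chance alone. A structure of the samples is not excluded, above all in PANC-1, where the split with 3459 kept only 2 control libraries as controls. In the others the highest split kept all 3, and splits that kept fewer gave at most 0, 618 and 157. For the number of lists chance cannot be excluded: 51, 25, 21 and 16 of 100 splits gave as many, with 3, 6, 5 and 9 lists against 10, 9, 6 and 11 for the highest other. For the overlaps these splits decide nothing, since the other splits share no gene and leave no level to compare with: 1 split of 100, the real one, gave as many for 21 (MDA-MB-468 and PANC-1), 29 (MDA-MB-468 and WiDr), 387 (PANC-1 and WiDr), 412 (WiDr hairpins and guides) and 2 genes (all lines), each with 0 for the highest other. Against independent lists the 387 and the 2 are no clear excess, with 188 up and 201 down expected for the first and 0.596 up and 0.806 down for the second.

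The splits of 6 libraries number 10, which are too few for a single construct. The real and highest other counts were 332 and 0 for hairpin 1, 511 and 4157 for hairpin 2 and 64 and 0 between hairpins in MDA-MB-468, with 2 splits as large for hairpin 2 and 1 elsewhere. In PANC-1 they were 4566 and 4203, 5053 and 1, and 16 and 0. In WiDr with hairpins they were 6871, 6403 and 6071 with 0 each, and with guides 6100 and 0, 3731 and 1, and 5040 and 0.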
